A study of Rattus norvegicus with 8 samples.

How the data were processed

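Liver RNA from male Fischer 344 rats was measured on oligonucleotide microarrays after transcription into digoxigenin-labelled cRNA with a chemiluminescent kit, per the labels' protocols. There were 8 samples, 4 from rats on the control diet (CON) and 4 from rats on the methionine-restricted diet (MR), and each group was taken from the sample titles. The deposited series table held values, read here as log2, for 26857 probes on the 8 arrays, with 0 missing values and a range of 5.09 to 21.1. The authors' scale, background correction and normalization are not given in the sources used here. Base 2 was inferred from the range of the values and is stated by no source, so every fold given assumes it. No centring per probe was seen. The median of each of the 8 columns was 9.23, and the sorted columns differed from each other by at most 0.00398, which is the pattern left by quantile normalization between arrays. Such a step removes any difference in overall signal between the arrays, so a change is relative to the bulk of the probes. The median change of the tested probes was -0.0042.

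A deposited scanner table with signals, their errors, signal-to-noise values and flags was also read. Its 60 measurement columns, for 12 arrays, carried no name that matches a sample, so they were used in no step. Only its gene identifier column was used, and all 26857 probe numbers of the series table were found in it. The scanner table also held 322 control probes that are not in the series table. The design had set these scanner signals, with filters on signal-to-noise and spot quality, as the main values, and the series table for the case that the scanner values were not usable. That case applied, so the series table became the main values and the filter was the one set for data without signal-to-noise. Probes were tested if their mean log2 value over the 8 arrays was above the 25th percentile of all probes, a value of 8.13, which kept 20142 probes. No detection call was available for any single probe, and array number limits the precision.

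Gene names were limited. Of the 26857 probes, 26800 carried an rCG identifier and 57 a RefSeq NM accession. Through a current rat RefSeq gene table (assembly GRCr8, used for names only), 34 of the 57 accessions and 1 rCG identifier, listed there as a synonym, gave a symbol. This named 35 probes for 34 symbols, of which 25 probes passed the filter. The other identifiers were not paired with symbols in the files or tables used here. Among the named probes, Hbb-b1, Cebpb, Hsd17b6, Atf4 and Ugt2b had mean log2 signals above 12, whereas Slc7a2 had 8.31 and St6gal1 7.83. Probes can also read near-identical family members, such as the globins or the eosinophil ribonucleases, and this could not be checked without probe sequences.

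Each probe was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, MR minus CON, all 8 arrays, no block). P-values were adjusted by the Benjamini-Hochberg method over the 20142 probes, with a threshold of 0.05. Errors are SDs over 4 arrays, or standard errors and 95% intervals from the fit. The fitting code was tested on simulated data with the means and spreads of the real probes. Of 200 probes changed in a simulated comparison of MR with CON among 20142, it called 0% at a log2 change of 0.5, 14.5% at 1 and 65.0% at 2. The changed probes were drawn at random from all signal levels, and dim probes varied more between arrays. The shares are averages over these levels, and recovery by level was not simulated. The adjustment is stricter when few probes change. These shares may therefore understate recovery in the real data, where 12.6% of tested probes were called.

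Choices made before the data were examined were the model, the threshold, the values and filter used without scanner data, 28 gene lists, 12 key genes and the naming rule. The rule named up to 12 genes in each direction with the largest change among probes past the threshold with no overlap of the groups, up to 4 members of each list, and the key genes. Of the 28 lists, 4 had a named probe: the amino acid response list had 2 of 31 members, and the erythroid, stellate cell and matrix, and exocrine pancreas lists had 1 each. The remaining 24 lists had 0, among them the methionine cycle, glutathione, lipid synthesis, cholesterol, fatty acid oxidation, bile acid, xenobiotic, hepatocyte, immune, endothelial and cholangiocyte lists. None of the 12 key genes was named. A list test needed 5 members, so 0 lists were tested. Unnamed probes are given by identifier for the 2 highest and the 2 lowest changes past the threshold without overlap.

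The alternatives were median scaling, cyclic loess, an offset of 50 on the linear signal, no filter, the replicate number as a block, array weights, a trended robust prior, an added minimum of 1.5-fold, and leaving out each array. A filter at the 50th percentile, the mean of the closest MR pair as 1 sample, and a repeated quantile step were added after the data were seen. Figures were drawn with matplotlib 3.10.9.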

Results

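The data were liver expression profiles of male Fischer 344 rats, an inbred strain, given purified amino acid diets for 20 months from an age of 32 days. The control diet (CON) contained 0.86% DL-methionine and the methionine-restricted diet (MR) 0.172%, which is 20% of the control content. Methionine is an essential sulfur amino acid. The comparison asked how long-term restriction changed hepatic gene expression. Each diet was represented by 4 arrays, with normalised log2 signals for 26857 probes. The log base was inferred from the range of the values, and folds assume base 2. The series describes the RNA as pooled, and the labels do not give the number of rats in a pool or whether each array had a pool of its own. The p-values therefore set each change against the spread between these arrays, which may be partly technical. They may then leave out part of the spread between rats and be too small.

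The arrays separated by diet. The first principal component held 34.6% of the variance, with scores from -64.5 to -43.2 for the 4 CON arrays and from 41.8 to 65.3 for the 4 MR arrays. Over the 20142 tested probes, the correlation between arrays was 0.937 to 0.949 within CON and 0.944 to 0.969 within MR. Between the diets it was 0.912 to 0.937. Among probes with a mean signal above the upper quartile of all probes, arrays of one diet differed by a median of 0.152 to 0.226 log2 units, and arrays of different diets by 0.320 to 0.450. The median SD of a probe was 0.38 in CON and 0.38 in MR. No pair of arrays of one diet held the same values, and at most 1.98% of probes agreed within 0.01 log2 units in any such pair. These correlations run across probes of the same arrays, and probes are not independent replicates.

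**Figure D1:**
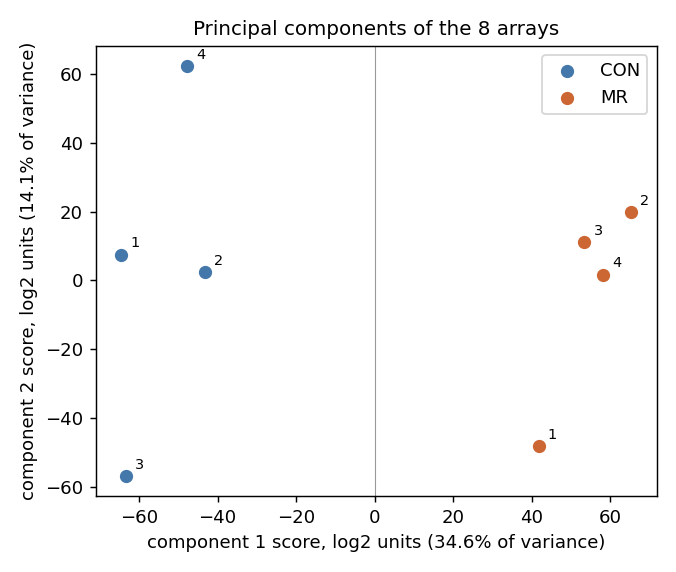
Scores of the 8 arrays on the first and second principal components of the 20142 tested probes, in log2 units, with the share of variance on each axis. Points are arrays, coloured by diet and numbered by replicate; all 4 CON arrays lie at or below -43.2 and all 4 MR arrays at or above 41.8 on the first component.

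Between the MR and CON arrays, 2532 of the 20142 tested probes, or 12.6%, differed and are called changed here. Of these, 1209 were higher and 1323 lower in MR than in CON (limma, Benjamini-Hochberg adjusted p under the threshold of 0.05). The median size of a change was 2.05-fold. A change of at least 2-fold was found for 657 probes that rose and 691 that fell, and a change of at least 10-fold for 43 that rose and 58 that fell. At the far end, 4 probes rose and 18 fell by at least 32-fold, and 0 rose and 8 fell by at least 100-fold. The 4 MR values lay wholly above or below the 4 CON values in 2504 of the 2532 changed probes, and in 22.1% of all tested probes, where chance gives 2.86%. The count fell when 1 array was left out, with fewer samples in each fit. Over these fits there were 753 to 1180 higher and 786 to 1136 lower probes. The lowest counts were 791 higher and 815 lower without CON replicate 1, and 826 and 854 without CON replicate 3. They were 786 and 786 without MR replicate 2, and 753 and 828 without MR replicate 3. MR replicates 2 and 3, the closest pair by correlation, were also averaged as 1 sample, an alternative chosen after seeing the data. This gave 803 higher and 854 lower probes.

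Changes were called mostly among bright probes. When the tested probes were ranked by mean signal into 5 equal bins, the brightest bin, with mean log2 signals of 13.3 to 20.9, had 567 probes that rose and 557 that fell, which is 27.9% of 4029. The dimmest bin, with means of 8.13 to 8.53, had 36 that rose and 46 that fell, or 2.04% of 4029. The median SD between arrays was 0.163 in the brightest bin and 0.692 in the dimmest. From the dimmest bin to the brightest, changed probes moved by a median of 2.41-fold, 2.95-fold, 3.01-fold, 1.99-fold and 1.80-fold. These medians cover only called probes, and a probe with a larger SD needs a larger change to be called. They therefore do not show that dim probes responded more strongly.

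**Figure D2:**
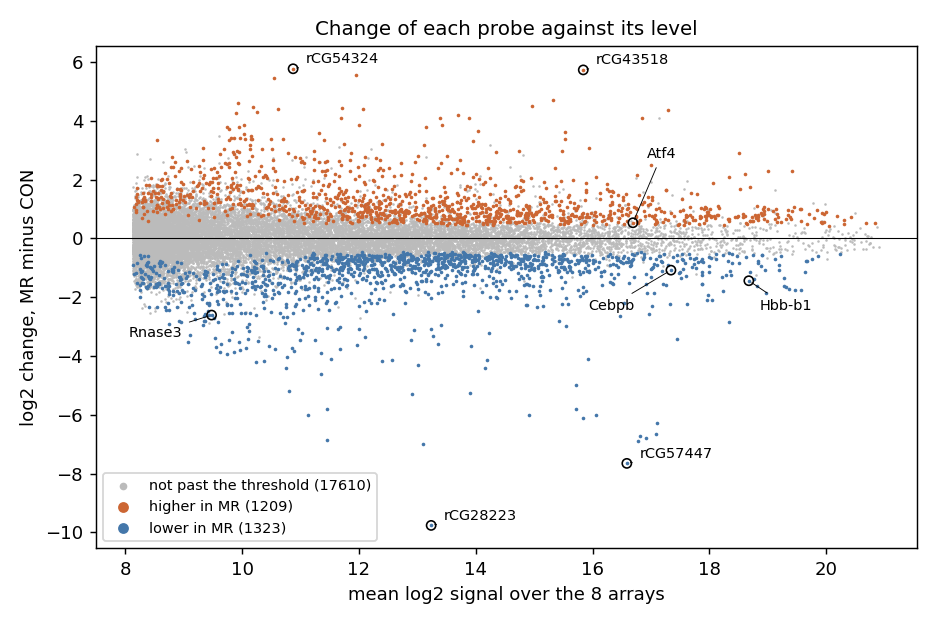
Log2 change (MR minus CON) of each tested probe against its mean log2 signal over the 8 arrays, with probes past the threshold coloured by direction. Circles mark the 4 named genes that changed and the 4 identifiers given in the text; the largest falls, down to -9.76, go further from 0 than the largest rises, up to 5.77.

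Among the 25 tested probes that carry a gene name, 4 changed: Hbb-b1, Cebpb and Rnase3 fell and Atf4 rose. At the rate of all tested probes, 3.14 of the 25 would have changed. Hbb-b1, which encodes a beta-globin chain of red blood cells, fell by 1.44 on the log2 scale (SE 0.203), or 2.71-fold with a 95% interval of 1.96 to 3.75. Its log2 signal was 19.39 ± 0.077 in CON and 17.96 ± 0.38 in MR (SD, n = 4 each). Cebpb, a basic leucine zipper transcription factor active in hepatocytes, fell 2.11-fold (interval 1.59 to 2.81), from 17.88 ± 0.20 to 16.80 ± 0.24. Rnase3, an eosinophil ribonuclease, fell 6.09-fold (interval 2.84 to 13.0), from 10.78 ± 0.62 to 8.17 ± 0.86. The limma adjusted p was 0.00418 for Hbb-b1, 0.00766 for Cebpb and 0.0113 for Rnase3, and in each case all 4 MR arrays lay below all 4 CON arrays. The MR level of Rnase3 was near the filter value of 8.13, so its fold is uncertain. Hbb-b1 and Rnase3 belong to families of similar genes, so their probes may not read these genes alone.

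Atf4, the transcription factor that drives the response to amino acid shortage, rose 1.45-fold (interval 1.16 to 1.81), from 16.42 ± 0.17 in CON to 16.96 ± 0.078 in MR (SD, n = 4 each). All 4 MR arrays lay above all 4 CON arrays, and the limma adjusted p was 0.0438. The call was lost when any single array was left out, with limma adjusted p from 0.0710 to 0.101, and with no filter on dim probes, at 0.0865. Over the 19 alternatives the limma adjusted p of Atf4 ran from 0.00292 to 0.132. The amino acid response list had these 2 genes, Atf4 and Cebpb, as its only named members, and they moved in opposite directions. Adjusted over these 2 genes alone, p was 0.00509 for Atf4 and 0.000638 for Cebpb in the same limma fit. An adjustment over 2 genes is slight, and it is no test of the list. Both genes also passed over all probes. Of the other lists with a named probe, the erythroid list had Hbb-b1 alone, which fell. Mmp2, a matrix metalloproteinase and the only named stellate cell and matrix marker, had a log2 change of -0.43 (SE 0.379, limma adjusted p = 0.508). Clps, the pancreatic colipase and the only named exocrine pancreas marker, had -0.96 (SE 0.526, limma adjusted p = 0.284). The other lists, among them the markers of hepatocytes, immune cells, endothelium and bile duct cells, had no named probe and were not analysed here.

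The remaining 21 named probes did not pass the threshold, and the 5 given next were chosen after their values were seen. Hsd17b6, a hydroxysteroid dehydrogenase, had a log2 change of -0.50 (SE 0.161, limma adjusted p = 0.0857), with signals of 17.56 ± 0.18 in CON and 17.06 ± 0.20 in MR (SD, n = 4 each). Itgae, an integrin subunit of epithelium-associated lymphocytes, had 1.54 (SE 0.495, limma adjusted p = 0.0857). Six3, a homeobox gene of the developing forebrain and eye, had 0.93 (SE 0.303, limma adjusted p = 0.0891). Ramp2, an accessory protein of calcitonin-family receptors, had -0.49 and Ugt2b, a glucuronosyltransferase, had 0.34, with limma adjusted p of 0.139 and 0.169. Hsd17b6 and Itgae passed with a trended robust prior, at adjusted p of 0.0125 and 0.0363 in limma, out of ranges of 0.0125 to 0.190 and 0.0363 to 0.189 over the alternatives.

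**Figure D3:**
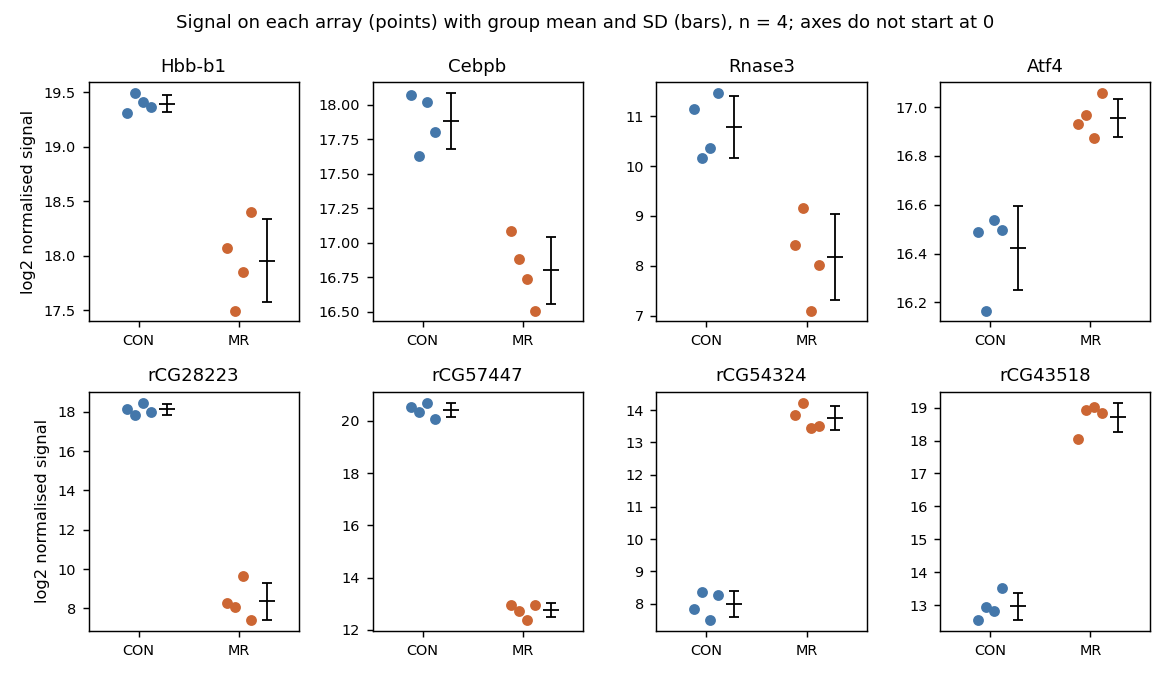
Log2 normalised signal on each of the 4 CON and 4 MR arrays (points), with the group mean and SD beside them, for the 4 named genes that changed and 4 unnamed identifiers. In each panel the 4 MR points lie wholly above or wholly below the 4 CON points, which was a condition for choosing the 4 identifiers. The axes differ between panels and do not start at 0.

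The largest changes were in probes without a gene name in the files or tables used here. The probe for rCG28223 fell by 9.76 on the log2 scale (SE 0.436), or 869-fold with a 95% interval of 433 to 1747. Its signal was 18.12 ± 0.26 in CON and 8.35 ± 0.93 in MR (SD, n = 4 each), and the MR level was at percentile 34.0 of all probes, so that this fold depends on how low signals were treated. The probe for rCG57447 fell 201-fold (interval 145 to 279), from 20.41 ± 0.27 to 12.76 ± 0.28. The probe for rCG54324 rose 54.7-fold (interval 36.1 to 83.0), from 7.98 ± 0.40 in CON, at percentile 19.5 of all probes, to 13.76 ± 0.36 in MR. That CON level was below the filter value of 8.13 and not shown to be above background, so the fold, its interval and its rank depend on how low signals were treated. The probe for rCG43518 rose 53.3-fold (interval 33.8 to 84.1), from 12.97 ± 0.41 to 18.71 ± 0.44. Their limma adjusted p-values were 4.27e-05, 6.77e-06, 4.27e-05 and 5.33e-05 in the order given. These 4 probes were chosen among changed probes without overlap of the groups, so their lack of overlap is no separate result.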

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

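The tests of array gaps, of bright probes, of red blood cell genes and of the 5 brightest falls were chosen only after the results they measure were seen, and so was the limit of 100-fold.

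The Atf4 signal of CON replicate 2 stood apart from the other CON arrays, at 16.17 against 16.49 to 16.54. Of the 32 groups of 4 values examined this way, 1 stood out, and chance alone gives about 1 in 20. Without this array the Atf4 change was 0.45 on the log2 scale, with a limma adjusted p of 0.0982, out of a range of 0.00292 to 0.132 over the alternatives.

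Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many as 2532 changed probes, the real one, and the highest of the others gave 0. The real split thus stood alone, at 1 of 35, the smallest share the design allows. That argues against chance in how these 8 arrays fell into the diets but does not exclude it. The other splits mix the diets, which widens the spread within their groups and lowers their counts. With pooled RNA, chance differences between pools or rats were not tested by the splits. A batch that follows the diets cannot be told apart from diet, because no batch could be tied to the samples.

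The falls of at least 100-fold in 8 probes, against 0 rises of that size, are the largest changes in the values as given. In 2 of the 8 the MR mean was below the median level of all probes. Without signal over background, this ranking and the contrast with the rises depend on how low signals were treated. In each of the 8, the lowest CON value exceeded the highest MR value by at least 5.06 log2 units, or 33.3-fold. The falls were thus not carried by a few arrays. Choosing probes by a large mean fall and a low adjusted p favours such a gap, so it is no separate test of aberrant arrays. Whether several probes read near-identical transcripts stays open for the 8 as a set: their deviations from the group means had a mean pairwise correlation of 0.240, at percentile 87.2 of 10000 random sets of probes that fell, matched on level, whose median was 0.089. For the 5 of them with a CON mean above 20, the correlation was 0.570, above the 95th percentile of such sets, 0.441. The random sets were matched on level and not on spread. Among the 5, the MR SD was 0.28 for rCG57447 and 0.95 to 1.18 for the others. Whether sets of equally variable probes would correlate as much was not tested. A family of similar transcripts or a gene read by several probes could give such a correlation. Separate transcripts regulated together by the diet would move alike too, and this stays open.

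Hbb-b1 was the brightest named gene that changed. The 200 probes nearest to it in level had a median change of 0.018, with quartiles of -0.36 and 0.58. Of these 200, 4 fell as far, so Hbb-b1 fell further than most probes of its level. Columns equalised between arrays hold such a median near 0. It therefore cannot decide whether the normalization shifted bright probes. Less red blood cell RNA in the MR livers may account for the fall, but this could not be tested: only 1 of the 10 erythroid genes on the list was named, where 3 were needed. An effect of the diet on Hbb-b1 itself stays open too.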

How the results depend on the processing

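Changed probes numbered 1209 higher and 1323 lower in MR, and the counts stayed within 1.5 times of these under median scaling, cyclic loess, the offset of 50, no filter, array weights, the trended robust prior, the 1.5-fold minimum and, added after seeing the data, the 50th percentile filter and a repeated quantile step. Across them the counts ran from 913 to 1668 higher and from 954 to 1854 lower. Median scaling and the repeated quantile step hardly moved the values, which were already equalised, and so say little. With the replicate block, 444 probes were higher and 483 lower, of which 425 and 464 were among the main calls. The numbers did not pair the samples: deviations of the 4 same-numbered pairs correlated between -0.040 and 0.053, and 2 of 8 arrays matched their own number best. The block uses up 3 degrees of freedom. With MR replicates 2 and 3 averaged as 1 sample, also added after seeing the data and with fewer samples, the counts were 803 and 854. Leaving out 1 array gave 753 to 1180 higher and 786 to 1136 lower probes, with fewer samples in each fit; the counts without CON replicate 1 were 791 and 815, without CON replicate 3 826 and 854, without MR replicate 2 786 and 786, and without MR replicate 3 753 and 828. Of the alternatives, no filter, the replicate block, the robust prior, the 1.5-fold minimum and the 50th percentile filter leave each log2 change as it is. No sign could change under them. The 4 identifiers were chosen for their large changes, which favours keeping their side of the threshold. Of 283 values of named genes and identifiers under the alternatives, 267 kept their side of the threshold and 0 changed sign. Of the 13 that lost it, 12 were Atf4, including the replicate block (adjusted p = 0.132 in limma) and the 1.5-fold minimum, and 1 was Rnase3 with the replicate block (adjusted p = 0.0523, range 0.00269 to 0.0523); Atf4 ranged from 0.00292 to 0.132. Adjusted p ran from 6.05e-05 to 0.0407 for Hbb-b1 and from 0.000152 to 0.0443 for Cebpb. The other 3 gained it: Hsd17b6 under the robust prior and the 50th percentile filter, and Itgae under the robust prior; the cause was not tested. Alternatives set in advance and not run were those based on signal-to-noise, spot quality, scan batches and list tests, since these values could not be tied to samples or the lists had too few named genes. The series table, set as an alternative, had become the main values. Without signal over background, folds of dim probes stay uncertain.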

Other observations

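Probes that share an identifier were compared with each other after the data were seen. Of 308 identifiers with 2 tested probes each, at least 1 probe changed in 94, and in 75 of these the 2 probes had log2 changes of the same sign. Both probes changed in 23, and in 22 of these in the same direction. In the pair that disagreed, the dimmer probe had a mean log2 signal of 8.27, near the filter value of 8.13. In the other 71 identifiers only 1 of the probes passed the threshold. Across identifiers, the log2 changes of the 2 probes correlated at 0.347 over all 308, at 0.516 where both were in the 2 brightest of 5 equal bins of signal (119 pairs) and at 0.163 where both were in the 3 dimmer bins (95 pairs). These correlations are across genes, which are not independent replicates.

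By correlation, the closest pair of arrays was MR replicates 2 and 3, at 0.969, against 0.954 for the next closest pair in MR. By the median difference over bright probes, CON replicates 2 and 3 were slightly closer, at 0.1523 log2 units against 0.1534. The deviations of MR replicates 2 and 3 from the MR mean correlated at -0.056. The other 5 pairs of MR arrays lay between -0.479 and -0.329. Deviations from a mean of 4 arrays correlate negatively by construction.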
